A study of Mus musculus with 32 samples.

How the data were processed

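Liver RNA was extracted with TRIzol and sequenced on an Illumina HiSeq instrument as paired reads of 150 bases, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, StringTie, RSEM and DESeq2 and the mouse build GRCm38, without versions, order or roles. Which of these made each value is not given in the sources used here.

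There is 1 table per experiment. Its library columns hold a signal, the expression value per gene and library that the authors deposited after their own normalisation, rounded to 0.01; whether it is TPM or FPKM is not stated. The header of the comparison columns is shifted against their content, and the table of T carries the column names of P. From the values, the authors deposited a linear fold change (a ratio), then its log2 fold change, then an unadjusted p-value and an adjusted p-value from their test. Every listed gene has a log2 fold change beyond 1 in either direction and an unadjusted p below 0.05, and the genes that did not pass were not used here. The authors' adjusted p equals 1 for 116 genes of P and 103 of T. Because a table holds part of the genes, its sum is not the depth; depth per library is unknown and no interval from counts is given. Most genes are low, with a mean below 1 for 195 genes of P and 220 of T, which limits their precision.

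Groups follow the treatment label of each library. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), two-sided, within each table, with Benjamini-Hochberg adjustment over the listed genes and a threshold of 0.05; fold changes of means are ratios of arithmetic means of the deposited values. The tables were not compared in level, only in their differences, through the interaction of treatment and experiment in limma over the 15 shared genes. A count model was not applied, as the values are not counts, so the planned DESeq2 alternative was not run. Permutation tests used all 12870 assignments of 16 libraries (3432 for 14), and 100000 resamples for the difference between experiments. They were run in Python 3 with numpy and scipy. The tests, alternatives, 28 gene lists and the naming rule were fixed before the data were examined. On simulated data for T, limma recovered 25 of 30 genes changed by 1 and 30 of 30 changed by 2 on the log2 scale, and called 2 of 246 unchanged genes; for P these were 27 of 30, 30 of 30 and 5 of 182. The permutation test recovered 30 of 30 genes shifted by 3 SD in each simulated experiment, and called 0 of 276 unchanged genes for T and 2 of 212 for P. Both simulations used normal values, independent between genes and without preselection. Their rates of false calls therefore do not carry over to the listed genes.

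Named genes are, per experiment, the 10 largest rises and 10 largest falls among genes passing the threshold with a mean of at least 1 in the higher group, up to 4 genes of each list with the smallest p, and the shared genes with the smallest larger p or a called difference. Not every gene that the rule takes is named. Models without a symbol are counted but named only where fewer than 5 others are left. Under the labels no gene of T passes, so for T the first part of the rule was applied to the 14 libraries without 16 and 18; Gm43558, Gm37027, Lgals3, Il1b, Cd14, Adgre1, Timd4, Trem2, Gpnmb, Ccl6, S100a9, Gpm6a, C1qtnf9, Scn3a, Kif23 and Gm47528, and genes of the other observations, are named outside the rule, after their values were seen. List direction was tested with Fisher's exact test among listed genes for lists with at least 3 members; enrichment against all genes was not tested, since the genes that could have passed are not given. Of the 28 lists, 10 had no gene in either table: bile acids, fatty acid oxidation, glucose and insulin, female-biased genes, circadian clock, GHB and GABA handling, endothelial cells, amino acid catabolism, blood cells and muscle. Gene identifiers were matched to GENCODE M21 (GRCm38): 242 of 242 in P and 305 of 306 in T. In that annotation Marco lies on chromosome 1 from 120474538 to 120505024, Cd5l on chromosome 3 from 87357881 to 87371073, Cfd on chromosome 10 from 79890853 to 79892655, Hamp on chromosome 7 from 30942368 to 30944032 and Upk3b on chromosome 5 from 136038496 to 136046487.

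No libraries were duplicates: Spearman's rho between libraries was 0.52 to 0.87 in P and 0.45 to 0.86 in T. Alternatives were smaller pseudocounts (0.1 and 0.01), a mean of at least 1, limma with trend and robust fitting, permutation and rank tests, a threshold of 0.01, each library left out, and libraries 16 and 18 left out or exchanged. Leaving out vehicle libraries 33, 34 and 35 of P, or libraries 1 to 4 of T, was added after the data were seen.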

Results

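Liver RNA of C57BL/6J mice was sequenced in a study of sodium oxybate (SXB), the sodium salt of gamma-hydroxybutyrate and a drug for narcolepsy, and body weight in developing and in established obesity. There were 2 experiments, called P and T after the letters in the library names, each with 8 vehicle and 8 SXB libraries, 32 in all. The labels do not say which letter stands for which form of obesity. Library numbers were 19 to 36 in P and 1 to 18 in T, and nothing in the labels states that each library came from its own mouse, so p-values measure the spread between libraries. The deposited table of P holds 242 genes and that of T 306 genes, each already selected by the authors on these same libraries for a log2 fold change beyond 1 in either direction and an unadjusted p below 0.05. Counts below are therefore counts among preselected genes and are not independent evidence of an effect. Values are the authors' normalised expression values, and sequencing depth is unknown.

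In experiment P, genes of macrophages were lower with SXB. Marco, a scavenger receptor of resident liver macrophages, had a mean of 2.39 ± 0.789 (SD, n = 8) with vehicle and 0.652 ± 0.304 (n = 8) with SXB, 3.66-fold lower. Cd5l, secreted by tissue macrophages, fell 2.04-fold from 14.02 ± 3.55 to 6.88 ± 1.23, and C1qb, a chain of complement C1q, fell 1.94-fold from 49.3 ± 14.5 to 25.4 ± 4.47. Lyz2, the lysozyme of myeloid cells, fell 2.09-fold and Ctss, the lysosomal protease cathepsin S, fell 1.97-fold. In each of these 5 genes all 8 SXB libraries lay below the vehicle median.

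**Figure D1:**
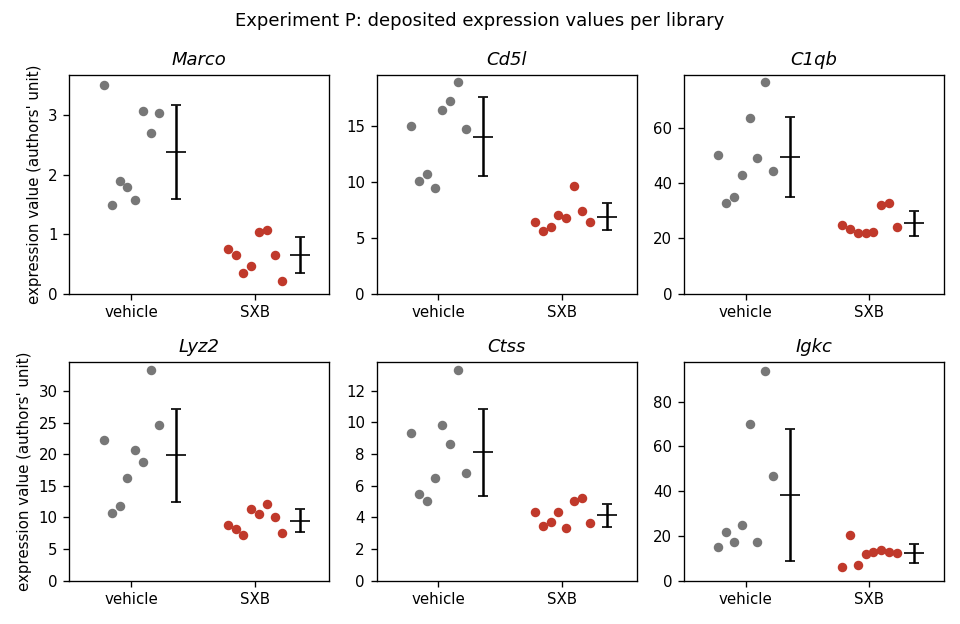
Deposited expression values (authors' unit, linear axis from 0) of 6 genes in experiment P, 1 point per library, with vehicle in grey and SXB in red, and the mean ± SD at the right of each group. For Marco, SXB values reach 1.07 at most and vehicle values start at 1.5, while the ranges of the other 5 genes overlap.

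On the log2(value + 1) scale, which understates changes of low genes, the differences of SXB minus vehicle were -1.02 (SE 0.15) for Marco, -0.91 (SE 0.14) for Cd5l, -0.90 (SE 0.16) for C1qb, -0.93 (SE 0.20) for Lyz2 and -0.79 (SE 0.16) for Ctss. Their limma adjusted p-values were 0.00113, 0.00113, 0.00138, 0.00305 and 0.00268. The table holds 13 of the 36 genes of the macrophage and monocyte list, all 13 lower with SXB, except that Gpnmb was 0.02 higher without vehicle libraries 33, 34 and 35. Of these, 10 passed limma over all listed genes and 11 passed when adjusted over the list alone. The other members that fell were Lgals3, Il1b, Cd14, Adgre1 and Timd4. Trem2, Gpnmb and Ccl6 did not pass, with log2 differences of -0.43, -0.16 and -0.62. The direction test could not set this list apart as lower, since 201 of the 242 listed genes were lower. Even with all 13 lower, Fisher's exact test, two-sided, gave p = 0.133 (adjusted p = 0.31 over 7 lists tested), so this is no evidence against the list.

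Of 9 immunoglobulin genes in the table of P, a group not fixed in advance as a list, 5 fell, and 3 without vehicle libraries 33, 34 and 35. Igkc, the constant region of the kappa light chain, fell 3.15-fold from 38.3 ± 29.4 to 12.2 ± 4.36 (log2 difference -1.34, SE 0.38, limma adjusted p = 0.0167). The variable segment Igkv3-2 fell 4.69-fold (log2 difference -1.05, SE 0.32), the heavy chain gene Ighg2b fell 14.4-fold (-0.97, SE 0.36) and the lambda light chain gene Iglc2 fell 2.29-fold (-0.58, SE 0.19). Without vehicle libraries 33, 34 and 35, Ighg2b at -0.32 and Iglc2 at -0.50 did not pass, while Igkc and Igkv3-2 did. Iglc2 also did not pass without vehicle library 35 (-0.51) or SXB library 19 (-0.51) alone, and the fall of Ighg2b in experiment P did not pass when 1 of vehicle libraries 33 to 36 or any 1 SXB library was left out (-0.73 to -0.998). Ighg2c, at -0.89 (SE 0.35, limma adjusted p = 0.0566), did not pass, though its adjusted p in the authors' test was 0.00969. Segments of this family are alike in sequence, so the split of reads between them is uncertain. Of the lymphocyte and neutrophil list, 5 genes are in the table, all lower (2 were higher without vehicle libraries 33, 34 and 35), of which Igkc and Iglc2 passed, and 3 passed when adjusted over the list alone. The direction of this list did not pass (Fisher's exact test, two-sided, adjusted p = 0.592), and could not have passed as lower, with all 5 already lower. The neutrophil granule genes S100a9 and Ngp did not pass (log2 differences -0.58 and -0.19), and both changed sign without vehicle libraries 33, 34 and 35.

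Among the largest falls were also Wfdc17, a small secreted protein of macrophages (33.9 ± 10.6 to 15.8 ± 3.85, 2.14-fold), the pseudogene Obox4-ps1 (3.06-fold) and the unnamed models Gm43558 and Gm37027. The interferon-response gene Ifit3b fell 2.01-fold (log2 difference -0.37, SE 0.09, limma adjusted p = 0.00622). Cidec, which coats lipid droplets, was 5.6 ± 4.87 with vehicle and 2.6 ± 0.931 with SXB and did not pass (log2 difference -0.68, SE 0.30, limma adjusted p = 0.0771), though as the only listed gene of the lipid storage list it passed adjusted over the list alone. Without vehicle libraries 33, 34 and 35 its difference was -0.18 and it no longer passed over the list alone. The acute phase genes Orm2 (-0.92, SE 1.17) and Saa3 (-1.14, SE 0.82) did not pass and were higher with SXB without vehicle libraries 33, 34 and 35. Asns, Mthfd2 and Cdkn1a, which were then higher too, Fosb, Gsta1 and the keratin gene Krt7 did not pass either, with log2 differences from -0.62 to 0.06. Of these, Fosb had an adjusted p of 0.00817 in the authors' test. Vehicle libraries 33, 34 and 35 held the highest Orm2 values in the group, up to 896.8 against 163.4 at most with SXB, and their sums of listed values were 1095, 1626 and 708 against 313 at most in the other vehicle libraries. They were picked for these sums, and only from the vehicle group. SXB library 25, with 163.4 for Orm2, was kept, though vehicle library 35 held 140.1. Leaving them out therefore favours sign changes of genes high in them, which are no evidence of a rise with SXB. The mitochondrial gene mt-Co3 was listed between 0 and 44.3 and did not pass (limma adjusted p = 0.217), though its adjusted p in the authors' test was 0.00313.

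In all, 94 of 242 genes passed limma at an adjusted p of 0.05, 10 higher and 84 lower with SXB. None of the 10 higher genes reached a mean of 1; they include Upk3b, Gpm6a and C1qtnf9. The authors' deposited table gives an adjusted p below 0.05 to 50 genes, 1 higher (mt-Co3) and 49 lower, 43 of which are among the 94. Leaving out vehicle libraries 33, 34 and 35, a choice made after seeing the data, gave 54 genes (4 higher, 50 lower), of which 9 were genes of the macrophage list, and moved Orm2, Saa3, Asns and Cdkn1a to higher with SXB.

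In experiment T, the 6 listed genes of the acute phase list were higher and the 7 of the lipid storage list lower with SXB under the labelled groups, though no gene passed the test and Saa1 and Saa4 were lower without libraries 1 to 4. Hamp, which encodes the iron hormone hepcidin, had a mean of 12154 ± 8947 (SD, n = 8) with vehicle and 18625 ± 4911 (n = 8) with SXB. Cfd, the complement protease adipsin, was 13.1 ± 21.2 with vehicle and 2.34 ± 4.42 with SXB, and G0s2, an inhibitor of the lipase ATGL, was 138.7 ± 76.4 and 66.0 ± 46.4. By limma 0 of 306 genes passed, with 90 at an unadjusted p below 0.05. Exact permutation and exact rank-sum tests passed 0 genes too, and 97 and 92 genes had unadjusted p-values below 0.05. Of the listed genes 148 were higher and 158 lower with SXB. Library 16, labelled vehicle, and library 18, labelled SXB, are each listed in the block of columns of the other group. The fold changes recomputed from the library values under the labels differed from those in the authors' deposited table by a median of 0.43 on the log2 scale, and by 0.15 with the groups of these libraries exchanged. Spearman's rho over the listed genes was 0.89 and 0.95, and 3 of 303 and 17 of 299 genes came within 1% (genes at 0 in a group left out). In P the median difference was 0.10, with 12 of 238 genes within 1%.

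**Figure D2:**
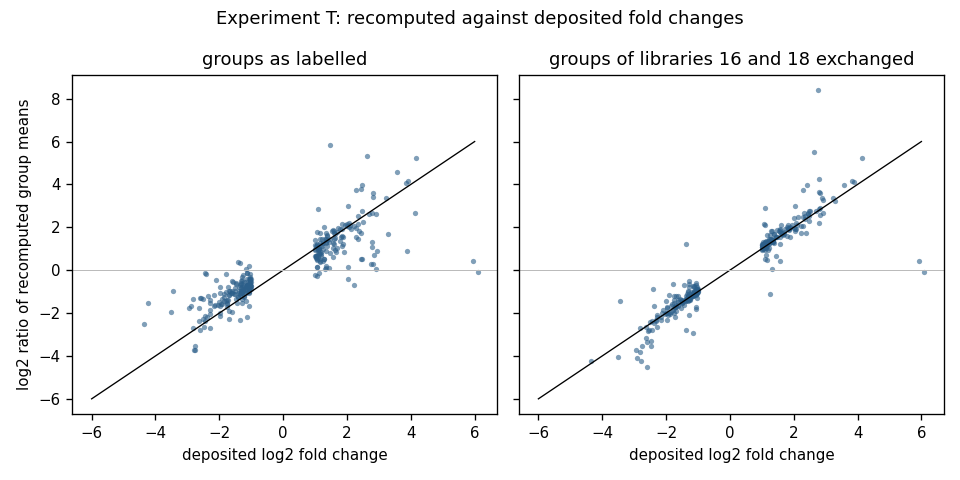
Log2 ratio of recomputed group means (SXB over vehicle) against the deposited log2 fold change in experiment T, 1 point per gene, with the line of equal values. Points lie closer to the line with the groups of libraries 16 and 18 exchanged (right, median difference 0.15) than under the labels (left, 0.43).

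Because of this conflict, the alternative without libraries 16 and 18 is described next, although the main test fixed in advance kept all 16 libraries. This alternative has 7 libraries labelled vehicle and 7 labelled SXB. Among them, Cfd, Gdf15 and G0s2 fell and Hamp and Eif4ebp3 rose. Cfd had a mean of 14.9 ± 22.2 (SD, n = 7) with vehicle and 0.801 ± 0.784 (n = 7) with SXB, 18.6-fold lower, or 8.47-fold without vehicle library 11, which holds 63.7. Gdf15, a stress-induced hormone, fell 4.64-fold (6.97-fold without SXB library 7) from 21.95 ± 16.8 to 4.73 ± 4.55, and G0s2 fell 2.62-fold from 153.5 ± 69.0 to 58.5 ± 44.4. Hamp rose 2.12-fold from 9239 ± 3751 to 19615 ± 4357. Eif4ebp3, a binding partner of the translation factor eIF4E, rose 3.32-fold from 34.05 ± 18.2 to 113.2 ± 37.0.

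**Figure D3:**
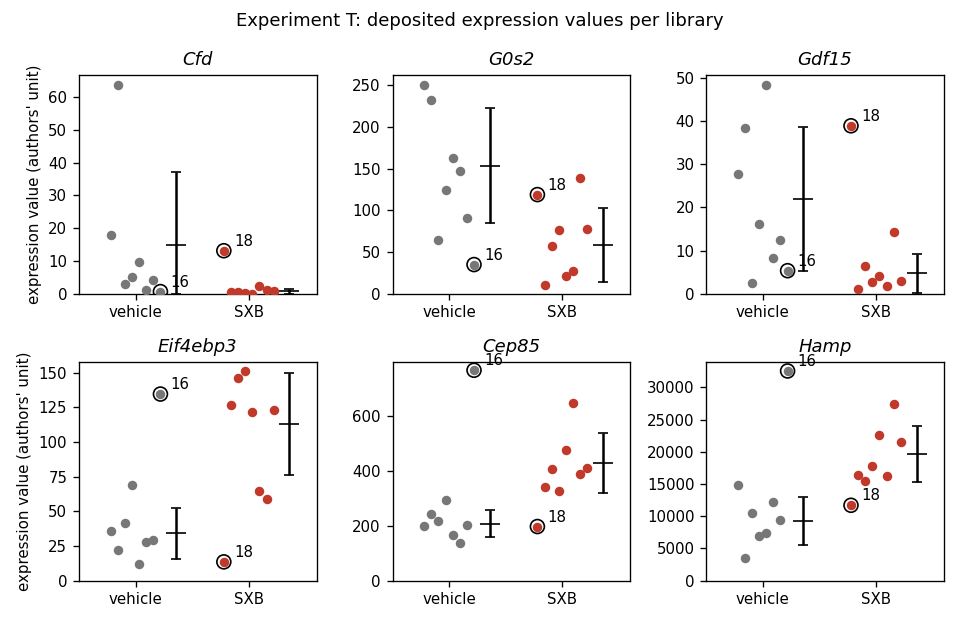
Deposited expression values (authors' unit, linear axis from 0) of 6 genes in experiment T, 1 point per library under the labelled groups, with vehicle in grey and SXB in red and libraries 16 and 18 circled. The mean ± SD leaves out the circled libraries (n = 7 per group, lower bars stop at 0); library 16, labelled vehicle, holds 134.7 for Eif4ebp3 and 32560 for Hamp, and library 18, labelled SXB, holds 13.5 and 11692.

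The log2 differences in these 14 libraries were -2.36 (SE 0.62) for Cfd, -1.88 (SE 0.59) for Gdf15, -1.66 (SE 0.52) for G0s2, 1.18 (SE 0.27) for Hamp and 1.79 (SE 0.34) for Eif4ebp3. Their limma adjusted p-values were 0.0339, 0.0428, 0.0428, 0.0263 and 0.0203. These adjust only over preselected genes and so do not bound the share of false calls. In the authors' test the adjusted p-values were 1.22e-05 for Cfd, 0.0351 for Gdf15, 0.225 for G0s2, 0.0467 for Hamp and 0.00127 for Eif4ebp3. Leaving out each of the 14 libraries in turn ended the call of Cfd 4 times, of Gdf15 and G0s2 11 times each, of Hamp 1 time and of Eif4ebp3 0 times. Under the labelled groups of all 16 libraries the same genes had differences of -1.68, -1.31, -1.23, 0.85 and 1.16, with limma adjusted p-values of 0.167 or 0.194. Further falls were found for the stress ligands of natural killer cells Raet1d (-1.56, SE 0.37) and Raet1e (-1.02, SE 0.26), which overlap on the same strand, the galectin gene Lgals1 (-1.46, SE 0.37), the B cell gene H2-Ob (-1.13, SE 0.34), the water channel gene Aqp8 (-1.11, SE 0.34) and Clstn3 (-1.05, SE 0.31), though the calls of H2-Ob, Aqp8 and Clstn3 ended in 9 of the 14 omissions each, of Raet1e and Lgals1 in 3 each and of Raet1d in 1. Further rises were found for Gm48199 (1.67, SE 0.37), Serpina1e (1.39, SE 0.43), Cep85 (1.04, SE 0.18) and E030018B13Rik (0.96, SE 0.30), though the calls of Serpina1e and E030018B13Rik ended in 10 of the 14 omissions each, of Gm48199 in 1 and of Cep85 in 0. Serpina1e has close paralogs, and Eif4ebp3 lies inside a longer annotated gene on the same strand, so reads of both can be shared.

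Of the lipid storage list, 7 genes are in the table of T and all 7 were lower in these 14 libraries. Mogat1, an enzyme of triglyceride synthesis (-0.59, SE 0.15), and G0s2 passed (the call of Mogat1 ended in 2 of the 14 omissions), and 2 passed adjusted over the list alone. Pparg, a regulator of fat storage (-0.86, SE 0.34, limma adjusted p = 0.0766), and Cd36, a fatty acid carrier (-0.78, SE 0.43), did not pass. In the authors' test the adjusted p was 0.0120 for Pparg and 0.137 for Cd36. Of the adipose tissue list, both listed genes, Cfd and Cidec, were lower (median -1.58), and Cfd passed, also adjusted over the list alone; vehicle library 11 holds the highest vehicle values of both and of Pparg. Of the acute phase list all 6 listed genes were higher and Hamp passed, while 2 passed adjusted over the list alone. Saa1 (1.43, SE 0.90), Saa4 (0.94, SE 0.43) and Socs3 (1.21, SE 0.44) did not pass, though their adjusted p-values in the authors' test were 0.0203, 0.0114 and 0.00801. With the groups of libraries 16 and 18 exchanged, 2 of the 6 acute phase genes passed limma, and 4 when adjusted over the list alone. The direction of both the lipid storage and the acute phase list missed the threshold, with an adjusted p of 0.0522 (Fisher's exact test, two-sided). All their listed members already went the same way, so the unadjusted p could not have been smaller. The members were chosen by the study on these libraries.

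Of the drug metabolism list, Cyp2a22 fell (-0.66, SE 0.16; call ended in 2 of the 14 omissions), 2 of 3 genes passed adjusted over the list alone, and Gsta1 (-1.01, SE 0.34) and Cyp2b10 did not pass over all genes. Cyp2b10 was -0.09 under the labels and 0.11 without libraries 16 and 18. Cd79b, a chain of the B cell receptor, fell (-0.31, SE 0.10, limma adjusted p = 0.0495), but its call ended in 13 of the 14 omissions. The macrophage genes Ccl2, Itgax and Mmp12 were lower with none passing, also adjusted over the list alone, and the matrix genes Timp1 and Mmp13 did not pass either. The pancreatic elastase gene Cela2a, which overlaps Ctrc on the same strand, rose from 0.42 ± 0.194 to 0.896 ± 0.352, though its call ended in 8 of the 14 omissions. Of the cell cycle list 4 genes are in the table, none passing and 1 passing adjusted over the list alone. Among the remaining list genes Myc (1.63, SE 0.73), Gadd45g (1.62, SE 0.55), Asns (0.93, SE 0.35), Hspa1a, Cspg5, Hmgcs1, Mvd, Pnpla3, Ube2c, Cdc20 and Cidec did not pass over all listed genes. Asns did pass adjusted over the unfolded protein and amino acid stress list alone, and Gsta1 over the oxidative stress list alone. In the authors' test the adjusted p was 0.0225 for Gadd45g and 0.0373 for Cidec.

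In all, 56 of 306 genes passed limma without libraries 16 and 18, 19 higher and 37 lower, and 24 of them are among the 43 with an adjusted p below 0.05 in the authors' deposited table. Of the genes said above to have risen or fallen, G0s2, Serpina1e, Cyp2a22, Cd79b and Cela2a are not among the 43. Their adjusted p-values in the authors' test were 0.225, 0.222, 0.198, 0.151 and 0.381. The count rests on single libraries: it was 3 without SXB library 2, 16, 19 and 25 without vehicle libraries 10, 4 and 11, 30 and 33 without vehicle libraries 8 and 15, and 29, 29 and 31 without SXB libraries 1, 13 and 12. The mitochondrial gene mt-Atp6 was 486 or more in libraries 1 to 4 (1 vehicle, 3 SXB) and 44.8 or less in all others, where it was listed at 0 in several, so a listed 0 can be a failed estimate. With libraries 1 to 4 as a term of the model 50 genes passed, without Gdf15 (-1.84), G0s2 (-1.27), Serpina1e, E030018B13Rik, H2-Ob, Aqp8, Cela2a and Cd79b, and 4 passed when these libraries were left out, none of them a gene said above to have risen or fallen (Cfd had a limma adjusted p of 0.149, Hamp 0.123 and Eif4ebp3 0.0573). With these libraries left out, fewer libraries remained. The differences of Cfd (-2.35), Hamp (1.21) and Eif4ebp3 (1.65) stayed about as large as in the 14 libraries. Those of Gdf15 (-1.16) and G0s2 (-0.70) were smaller than in the 14 libraries. Under the labels, the term and the omission each gave 0 genes.

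Whether SXB acted alike in both experiments could be compared for the 15 genes listed in both tables. Upk3b and Msln, markers of the mesothelium that covers organs, were higher with SXB in P and lower in T. Upk3b rose in P from 0.0413 ± 0.0356 to 0.136 ± 0.0825 (n = 8 each; log2 difference 0.12), against -0.16 in T. Msln differed by 0.14 in P and -0.16 in T. Ugt2b37, a glucuronosyltransferase, was -0.41 in P and 0.40 in T, Wif1, a secreted Wnt inhibitor, -0.20 and 0.39, and Tmc5 -0.11 and 0.15, though Tmc5 was 0.02 higher in P without vehicle libraries 33, 34 and 35. The difference between experiments passed limma for these 5 genes, with adjusted p-values of 0.00781 for Upk3b and Ugt2b37, 0.0224 for Msln, 0.0231 for Wif1 and 0.0403 for Tmc5. Of these 5 genes, only Upk3b in P passed within an experiment. The other 4 genes in P had limma adjusted p-values from 0.058 to 0.196, and all 5 in T 0.167 under the labels. Without libraries 16 and 18 Wif1 passed in T (0.0339), a call that ended in 5 of the 14 omissions. Its adjusted p in the authors' test of T was 0.0584.

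**Figure D4:**
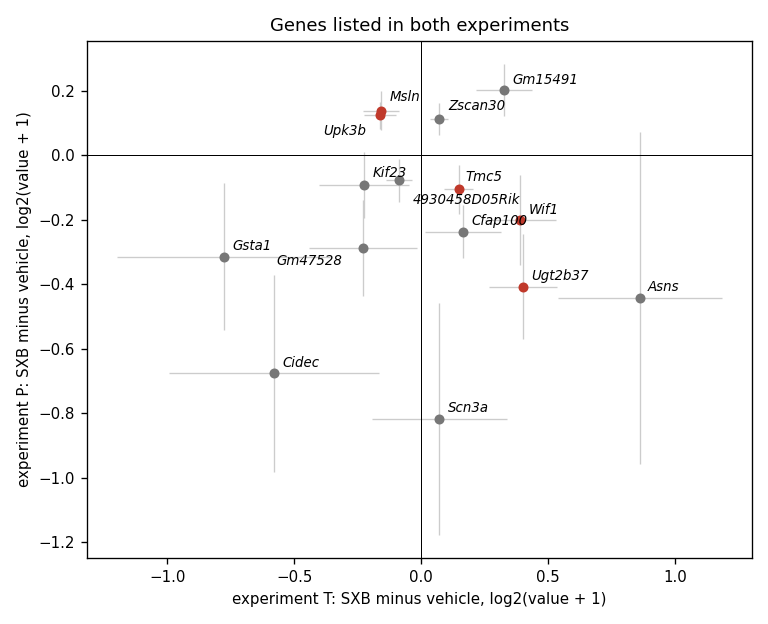
Differences of SXB minus vehicle on the log2(value + 1) scale in experiment T (horizontal) and experiment P (vertical) for the 15 genes listed in both tables, with bars of 1 SE. Red points are the 5 genes whose difference between experiments passed limma, all of them in quadrants of opposite sign, though Tmc5 was 0.02 higher in P without vehicle libraries 33, 34 and 35. The selection of the genes in each experiment favours such calls for genes of opposite sign.

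The rise of Upk3b in P did not pass without vehicle library 35 (0.12) or SXB library 25, 28 or 29 (0.11, 0.11 and 0.10), nor by the exact rank-sum test. Its adjusted p in the authors' test of P was 0.0870. The other 10 genes did not pass the test of the difference. Among them, Cfap100 passed within P (-0.24, limma adjusted p = 0.0364). Gm15491 passed in T without libraries 16 and 18 (0.37, limma adjusted p = 0.0424), a call that ended in 12 of the 14 omissions. It also passed with libraries 1 to 4 left out as well (0.57, limma adjusted p = 0.0143). Cidec (-0.58 in T, -0.68 in P), Gsta1, Gm15491, Gm47528, Kif23, 4930458D05Rik and Zscan30 had the same sign in both, which makes 7 of 15 (exact sign test, two-sided, p = 1.0), though Gm47528 and 4930458D05Rik changed sign in P without vehicle libraries 33, 34 and 35 and Kif23 in T without libraries 1 to 4. Cfap100, Asns and Scn3a had opposite signs, though Asns changed sign in P without vehicle libraries 33, 34 and 35 and Cfap100 and Scn3a in T without libraries 1 to 4 (Scn3a also without SXB library 1). All 15 genes were chosen by the study in each table, and most are low, with Upk3b below 1 in every library. Leaving out 1 of the 32 libraries ended the call of Tmc5 16 times and of the other 4 genes 0 times. Without libraries 16 and 18 the number of genes with a called difference was 6, Cfap100 being added, and without vehicle libraries 33, 34 and 35 of P as well it was 4, without Tmc5.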

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

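The tests of the exchange, the splits, the macrophage genes and the mesothelial genes below were chosen after their results or the values behind them had been seen. Of 172 groups of libraries of the named genes and sums, 52 held a library far from the rest by Dixon's criterion (0.526 for 8 libraries). Chance would give about 8.6 for normal values. The criterion was applied to the deposited values on the linear scale, some of them low. The excess over 8.6 therefore cannot tell abnormal libraries from skewed values in the 52 flagged groups.

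Vehicle library 16 of T stood apart in 10 of these: it held 767.5 for Cep85, 2.51 for Cyp2b10, 2.13 for E030018B13Rik, 134.67 for Eif4ebp3, 82.01 for Gadd45g, 6.71 for Gm48199, 32559.75 for Hamp, 408.74 for Saa1, 16.78 for Socs3 and 36616.98 for the sum of listed values. Library 18, labelled SXB, also stood apart in 10: 13.13 for Cfd, 1.48 for Cyp2a22, 38.91 for Gdf15, 7.81 for Gsta1, 1.67 for H2-Ob, 65.75 for Lgals1, 1.61 for Mogat1, 0.26 for Msln, 6.06 for Raet1e and 0.45 for Timp1. The listed genes fit a selection with libraries 16 and 18 exchanged, and many were named from the fit without them. That selection favours flags of these libraries, so the flags are not independent evidence about their labels. Vehicle library 34 of P stood apart with 0.5 for 4930458D05Rik, 23.61 for Asns, 39.43 for Cdkn1a, 16.87 for Cidec, 3.74 for Gsta1, 1.73 for Mthfd2, 265.09 for Saa3, 0.52 for Tmc5, 0.09 for Zscan30 and 8.73 for mt-Co3.

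Among the other libraries of T, vehicle library 4 held 9.41 for Ccl2, 3.9 for Pnpla3, 0.04 for Tmc5 and 6421.52 for mt-Atp6. Vehicle library 11 held 63.66 for Cfd, 24.46 for Cidec, 8.44 for Gsta1, 109.27 for Lgals1 and 13.14 for Pparg, vehicle library 14 held 8.91 for H2-Ob, and vehicle library 15 held 1.12 for Hspa1a. Of the SXB libraries, library 2 held 7.21 for Asns, 12.02 for Cspg5 and 7.16 for E030018B13Rik, library 3 held 4.39 for Ccl2, library 1 held 1.34 for Cfap100 and library 13 held 2.37 for Hspa1a. In P, SXB library 28 held 9.57 for Cd5l and 23.94 for Wfdc17, SXB library 30 held 1.23 for Fosb, SXB library 29 held 0.92 for Mthfd2 and vehicle library 31 held 2.19 for Fosb. The effects of SXB differed between experiments, P minus T, by -0.81 for Ugt2b37, 0.28 for Upk3b, 0.30 for Msln, -0.59 for Wif1 and -0.25 for Tmc5 on the log2 scale. These genes were selected in each experiment on the same libraries, so the differences are not independent evidence.

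The first pattern is that no gene of T passed under the labelled groups while 56 passed without libraries 16 and 18. A candidate explanation is that the labels of these libraries were exchanged, in the labels or in the table: of all 64 one-for-one exchanges, this one came nearest to the deposited fold changes, with a median difference of 0.15 against 0.43 under the labels and 0.37 for the next exchange. The genes were chosen on the grouping the authors used, so this tells how their table was grouped and not how the mice were treated. Of 100 splits of the 16 libraries, all 100 gave as many genes as the labelled one, since that gave 0, and the highest other gave 12; of 100 splits of the 14 libraries 1, the real one, gave as many as 56, and the highest other gave 23. Because the genes were chosen on nearly these groups, the splits cannot exclude chance in either case.

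The second pattern is the fall of macrophage genes in P. Without vehicle libraries 33, 34 and 35, the 3 with high acute phase values, 9 of the 13 list genes still fell. The median log2 difference of the 13 genes went from -0.651 to -0.54. The genes had been chosen on libraries that include the remaining ones, so most calls were likely to stay. A part played by these 3 libraries is therefore not excluded. A different amount of macrophages in the sampled tissue may account for the fall. The 13 genes rose and fell together within groups, with a mean pairwise correlation of residuals of 0.53 over 16 libraries (permutation p = 1e-04, the smallest that 10000 resamples can give). No other listed genes were set beside them. The correlation therefore does not tell cell amount from a factor shared by whole libraries or from shared regulation per cell. A change in transcription per cell, an effect of SXB on macrophage number and a difference in the piece of liver taken stay open, as no cell counts were analysed here. Of 100 splits of the 16 libraries 1, the real one with 94 genes, gave as many, and the highest other gave 2, but the genes had been chosen on this split, so chance cannot be excluded this way.

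The third pattern is that the mesothelial genes Upk3b and Msln were higher with SXB in P and lower in T, where only the rise of Upk3b in P passed within an experiment. Of a list written after the data were seen, 2 of 6 genes passed in P and 0 of 6 in T, and Nkain4 changed sign in T without libraries 1 to 4. A different amount of liver surface lining in the samples may account for it: within groups Upk3b and Msln rose and fell together, with Pearson's r of residuals of 0.75 in P (permutation p = 0.00112, adjusted p = 0.00336 over 3 relations) and 0.66 in T (permutation p = 0.00786, adjusted p = 0.0118), and Spearman's rho of 0.73 and 0.74 (permutation p = 0.00227 and 0.00154) over 16 libraries each. Without the 2 libraries farthest from the median, r was 0.68 and 0.70, and in T without libraries 16 and 18 it was 0.64 (permutation p = 0.0186). An effect of SXB on these cells that differs between the experiments, and a factor shared by whole libraries, were not tested and stay open.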

How the results depend on the processing

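The alternatives that leave out libraries 1 to 4 of T or 33, 34 and 35 of P, or combine another setting with leaving out 16 and 18, were chosen after seeing the data. For T, 56 genes passed without libraries 16 and 18, 90 with them exchanged (54 of the 56 among them) and 2 at pseudocount 0.01; without 16 and 18, 106 passed at pseudocount 0.1, 61 by exact permutation, 4 without libraries 1 to 4 and 50 with these as a term. Leaving out each library gave 0 to 0 under the labels and 3 to 76 without 16 and 18. For P, 26 of 47 genes with a mean of at least 1 passed (fewer genes tested), 36 at an adjusted p of 0.01 and 54 without vehicle libraries 33, 34 and 35 (46 of the 94 kept); each library left out gave 68 to 101, and pseudocounts, trend and robust fitting, permutation and rank tests 104 to 130. The called differences between experiments were 4 to 7 in the alternatives run for them (pseudocount 0.1, 16 and 18 left out, these and 33, 34 and 35 left out, each library left out). Of the list directions fixed in advance, those testable (7, or 1 among called genes only) passed in none of the alternatives run for them (16 and 18 left out or exchanged, 33, 34 and 35 left out, called genes only). The macrophage list in P could not pass as lower even with all its listed members lower, so this is no evidence against it. Spearman's rho with the deposited fold changes was 0.89 under the labels, 0.94 without 16 and 18 and 0.95 exchanged. Of the genes named by the rule that had not passed, Asns, Cdkn1a, Mthfd2, Ngp, Orm2, Saa3, Tmc5 and 4930458D05Rik changed sign in P without 33, 34 and 35 (0.26, 0.46, 0.017, 0.004, 1.09, 0.20, 0.016 and 0.002; with each library left out Mthfd2 ranged from -0.221 to 0.011), as did Gpnmb, S100a9, Ighg1 and Gm47528 (0.02, 0.25, 0.10 and 0.01), named outside it. The difference of Cdc20 in experiment T changed to -0.043 without 16 and 18 (by permutation too), -0.099 exchanged, -0.206 with pseudocount 0.1, -0.074 and -0.070 with libraries 1 to 4 left out or as a term, and ranged from -0.024 to 0.052 with each library left out. That of Cyp2b10 in experiment T changed to 0.108, 0.283, 0.234, 0.215 and 0.090 in the same settings and ranged from -0.2 to 0.106 with each library left out. Without libraries 1 to 4, Cfap100 changed to -0.082 (-0.060 also without 16 and 18), Saa1 to -0.152 and Saa4 to -0.037. Libraries 33, 34 and 35 were picked for high sums in the vehicle group only, which favours sign changes of genes high in them. The cause was not tested further. The planned DESeq2 fit was not run, since the values are not counts. No paired analysis was possible because no library number is shared between groups. Unknown depth limits the low genes.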

Other observations

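The gene groups in this part were listed after the data had been seen. These genes outside the macrophage list, chosen after their values were seen and not tested as a group, fell in P: Siglece (log2 difference -0.66, SE 0.16), Ear2 (-0.86, SE 0.17), Fcgr4 (-0.51, SE 0.16), Clec7a (-0.43, SE 0.12), Ncf1 (-0.39, SE 0.07) and Spic, a transcription factor of red pulp and liver macrophages (-0.32, SE 0.10), all with limma adjusted p-values below the threshold. All 9 immunoglobulin genes in the table of P were lower and 5 passed, of which 3 passed without vehicle libraries 33, 34 and 35, where 1 of the 9, Ighg1, was higher. Ighg1 (-0.96, SE 0.62) did not pass and reached 22.4 in 1 vehicle library. Fcrl1 (-0.10, SE 0.04, limma adjusted p = 0.0460) and Btla (-0.09, SE 0.03, limma adjusted p = 0.0215), the 2 genes of a B cell list in the table of P, fell in P. Both were low, with vehicle means of 0.144 and 0.111 and SXB means of 0.0638 and 0.0413.

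In T, 6 genes of a B cell list of 13 were in the table, all lower with SXB under the labels and in the 14 libraries, where H2-Ob and Cd79b passed (their calls ended in 9 and 13 of the 14 single-library omissions); Ighd (-0.37, SE 0.16), Fcer2a (-0.18, SE 0.08), Stap1 and Siglecg did not, and these 2 were higher under the labels without libraries 1 to 4 (Fisher's exact test of direction, two-sided, adjusted p = 0.0302 over 5 tests). Of the 2 immunoglobulin genes in the table of T, Ighd was lower. The other, Igkv6-32, is not in this B cell list and was higher under the labels and in the 14 libraries. Of a mesothelial list of 15, 6 genes were in each table. In P all 6 were higher (adjusted p = 8.58e-05 by Fisher's exact test), Upk3b and Gpm6a passed over all genes, and 5 passed adjusted over the list alone; Msln, Muc16, Upk1b and Krt7 were the others. In T Msln, Upk3b, Anxa8, Cldn15, Rspo1 and Nkain4 were all lower (adjusted p = 0.0302), none passing, except that Nkain4 was higher without libraries 1 to 4 or without vehicle library 6. All were low, below 1 in every library of T and P, and these lists were written after the genes in the tables had been seen, so the tests are not independent evidence. Krt7 and Krt19 of this list are also in the cholangiocyte list.

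Some genes were high in a few libraries and near 0 in the others. In P the mitochondrial gene mt-Co3 was 8.73 in vehicle library 34, 44.3, 43.0 and 4.88 in SXB libraries 24, 29 and 28 and 0.15 or less in the other 12 libraries. In T the pseudogene Idi1-ps1 was 10.5 in vehicle library 4, 6.37 and 7.07 in SXB libraries 1 and 3, 0.43 and 0.37 in SXB libraries 2 and 9 and listed at 0 elsewhere. In GENCODE M21, mt-Atp6 (chromosome M, 7927 to 8607) overlaps mt-Atp8 (7766 to 7969) and shares its last base with mt-Co3 (8607 to 9390).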
